A study of Caenorhabditis elegans with 2 samples.

How the data were processed

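ChIP-seq with an antibody against GFP was done on whole young adult worms with a zfh-2::GFP fusion at the endogenous locus, in 2 biological replicates of 1 group. Chromatin was sheared by sonication, per the labels. The deposited files are peak lists in build ce11, per the labels: for each replicate a thresholded list and a longer ranked list, made from that replicate's own alignments, and for the series 2 thresholded lists and 2 ranked lists made from both replicates together. The aligner, the peak caller and its control are not given in the sources used here. No control library was analysed here.

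Each deposited peak carries a score, which in the authors' lists is at most 1000 and follows the logarithm of the irreproducible discovery rate (IDR). All peaks of the conservative list had a score that corresponds to an IDR of 0.01 or less. Each also carries the authors' signal, whose scaling is not given in the sources used here and which was used to rank peaks within a list and, on log10 values, to correlate peaks matched between the replicates. The deposited ranked lists also give −log10 of the global IDR. Which of the 2 ranked series lists compared the replicates was found from its intervals: 89.8% of its first and 84.8% of its second matched intervals occur in the ranked lists of replicate 1 and replicate 2, and almost none of the other list's do. That list contains every interval of the conservative list with its score. Its 4 further columns of values for the matched peaks name no sample and were not used, so the planned signal correlation over that list was replaced by one over the replicates' own ranked lists. The lists hold no read counts, so depth is unknown and intervals cover counting of summits, genes or tiles only.

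Coordinates were compared with the WBcel235 reference. Its chromosome names match those of the lists apart from the prefix, and no peak ended beyond a chromosome's length. Gene positions came from Ensembl release 115. The summit of a peak was its start plus the listed offset. The 2 mitochondrial peaks of the conservative list were left out. In that list 358 peaks repeat the interval of another peak with a different summit. There were 747 pairs of neighbouring summits under 600 bp apart, at a median of 203 bp, and in 94.9% of them the summit at the higher coordinate was the weaker, so 1 summit per merged region was run as an added alternative.

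Promoter windows ran from 1000 bp upstream to 200 bp downstream of the 5' end of each protein-coding gene. Each summit was given 1 class, in the order promoter window, coding exon, untranslated region, intron, non-coding gene and intergenic. Shares were compared with 1000 circular shifts of all summits along each chromosome (two-sided empirical p). Gene lists (29) were tested by two-sided Fisher's exact tests against all other protein-coding genes, with conditional odds ratios and 95% intervals. Motifs (17, either strand) were counted within 50 bp of summits and of a flank 300 bp away on a random side, with an exact McNemar test. Adjusted p values are Benjamini-Hochberg values over the 29 lists, the 17 motifs, the 7 features, the 6 tests of unshared peaks or the 10 further features, with a threshold of 0.05. X chromosome shares were tested by exact binomial tests. Summits, genes and motif windows are not independent replicates, and with 1 group no test between samples was made. Shares have 95% Wilson intervals. GC content was taken within 50 bp of a position. GC-matched shares average, over the summits, the share of each class among all genome positions of the same GC content. Their p values (random-draw test) came from 1000 sets in which each summit's class was drawn at random by those shares. Summits were drawn singly, so their clustering was not kept, which can make these p values too small. GC-matched lists were drawn 10000 times within 50 groups of genes of like highest GC in the promoter window, after a first run with 10 groups that kept the same 4 of 7 lists. Both runs, all other GC matching and a set of 10 further features were chosen after seeing the data, and so was a scan of short words around summits, which is not reported. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

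The lists, motifs, windows, tests and most alternatives were fixed before the data were examined. The genes named are zfh-2 and unc-119, the protein-coding genes whose window holds 1 of the 15 strongest summits found in both replicates' own lists, up to 4 members of each list past the threshold with the highest signal, the 3 strongest unshared peaks of each replicate and the 3 strongest summits outside promoter windows. Alternatives were the other pooled list, the stronger 50% of peaks, each replicate's own list, other windows, 5' ends of all transcripts, the nearest 5' end within 5 kb, lists matched on the distance to the upstream gene, other overlaps and other motif windows.

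The tests were tested on simulated data. With no effect planted, circularly shifted summits gave a call for at least 1 of the 29 lists in 5 of 20 runs, so the list test called lists more often than its threshold states, and summits added to 40% of the axon guidance list gave its call in 20 of 20. The shift test called 0 of 20 sets of uniform positions and 20 of 20 sets with 10% of summits moved to gene starts. The motif test called any motif in 1 of 5 sets of shuffled windows and found TAATTA put into 200 windows in 5 of 5.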

Results

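The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for ZFH-2, a zinc finger homeodomain transcription factor of the nematode Caenorhabditis elegans related to vertebrate ZFHX3 and ZFHX4. The worms carried GFP fused to the endogenous zfh-2 gene, and chromatin was precipitated with an antibody against GFP. Whole young adults, collected at 64.5 hours after synchronisation as starved first-stage larvae, formed 1 group of 2 biological replicates. The lists give where peaks were called on the chromosomes and how far the 2 replicates gave the same peaks. No control library was analysed here, and the sequencing depth is unknown because the lists hold no read counts. The authors' peak signal was used to rank peaks within a list and, on log10 values, to correlate peaks matched between the replicates.

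Replicate 1 had 4283 thresholded peaks of its own and replicate 2 had 4696. The authors' conservative list, made from both replicates together, held 7087 peaks, and it is the peak set of every result below unless another list is named. It merged into 6386 regions that covered 2.45% of the genome, with a median peak width of 470 bp, and 2 of its peaks lay on the mitochondrial chromosome and were left out, which left 7085 summits. Of these peaks 48.3% (3419) overlapped a peak in both replicates' own lists and 27.9% (1977) in neither. Of the nuclear peaks of replicate 1, 76.4% (3271 of 4281, 95% Wilson interval 75.1 to 77.7%) overlapped a peak of replicate 2 by at least 1 bp, against a mean of 3.37% after circular shifts along each chromosome. In the other direction the share was 70.7%. Both were above every one of the 1000 shifts (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). Summits in the own lists had a mean GC content of 55.7% (replicate 1) and 56.9% (replicate 2), against 35.4% in the nuclear genome. Because shifts do not keep GC content, they cannot tell repeated binding from a shared dependence on GC. No GC-matched overlap was computed. Across the 3271 matched peaks, the signals of the replicates had a Spearman rho of 0.597 and a Pearson r of 0.455 on log10 values, as a description across peaks, which are not independent replicates. The Pearson r was 0.756 with 1 summit per merged region, a setting chosen after seeing the data. Matched summits lay a median of 21 bp apart.

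**Figure D1:**
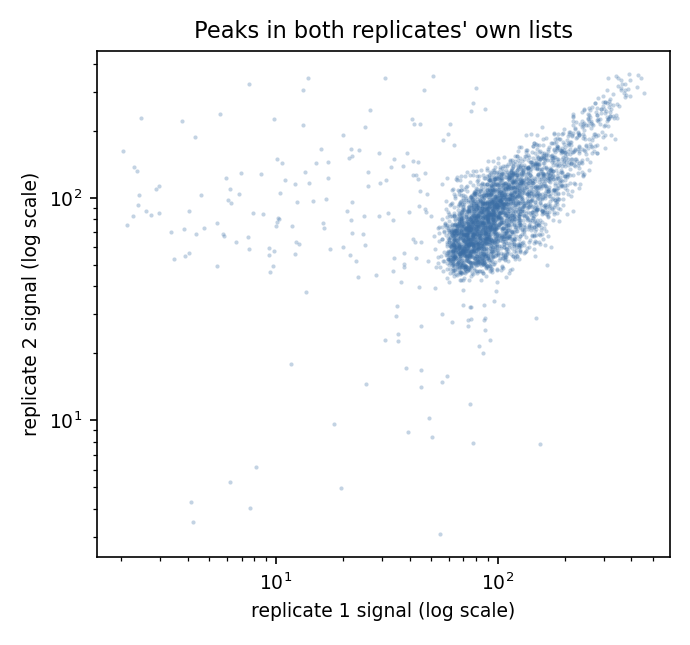
Signal of peaks matched between the replicates' own thresholded lists, replicate 1 on the x axis and replicate 2 on the y axis, both on log scales in the authors' signal units, with 1 point per matched peak (3271 points). Most points lie along a rising band (Spearman rho 0.597), and a scatter of points with a low signal in replicate 1 lies apart from it. Each replicate 1 peak was matched to the overlapping replicate 2 peak with the nearest summit. Further summits of 1 interval could thus share a match. With 1 summit per merged region, Pearson r on log10 values was 0.756 instead of 0.455.

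Of the 7085 summits, 37.8% lay in coding exons, 23.8% in the promoter window of a protein-coding gene (1000 bp upstream to 200 bp downstream of its 5' end), 20.2% in introns, 12.8% in intergenic sequence, 4.04% in non-coding genes and 1.41% in untranslated regions. The promoter share (95% Wilson interval 22.8 to 24.8%) was 1.12 times the 21.3% ± 0.626 (SD over 1000 shifts) found after circular shifts (two-sided permutation p = 0.002, the smallest possible). The coding exon share was 1.87 times its shifted mean of 20.2%, and the intron and intergenic shares were 0.648 and 0.603 times theirs, each with the same permutation p of 0.002. Summits inside the window of their nearest gene had a median position of -239 bp relative to its 5' end. Placement changed with signal. In the strongest 20% of summits the promoter window held 32.7% and coding exons 22.8%, while in the weakest 20% the values were 19.8% and 43.2%. By Fisher's exact test, the odds of promoter placement were 1.98 times higher in the strongest than in the weakest 20% (95% interval 1.66 to 2.36, adjusted p = 1.54e-14), and the odds of coding exon placement were 0.388 times as high (0.329 to 0.458, adjusted p = 3.82e-30, Benjamini-Hochberg over 7 features). Against genome positions with the same GC content as the summits, a comparison chosen after seeing the data, the promoter share was 1.18 times the expected 20.1%, the coding exon share 0.987 times the expected 38.3%, the intergenic share 0.808 times the expected 15.8%, and the intron share 1.02 times the expected 19.8%, with no intron difference detected (permutation p = 0.462).

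**Figure D2:**
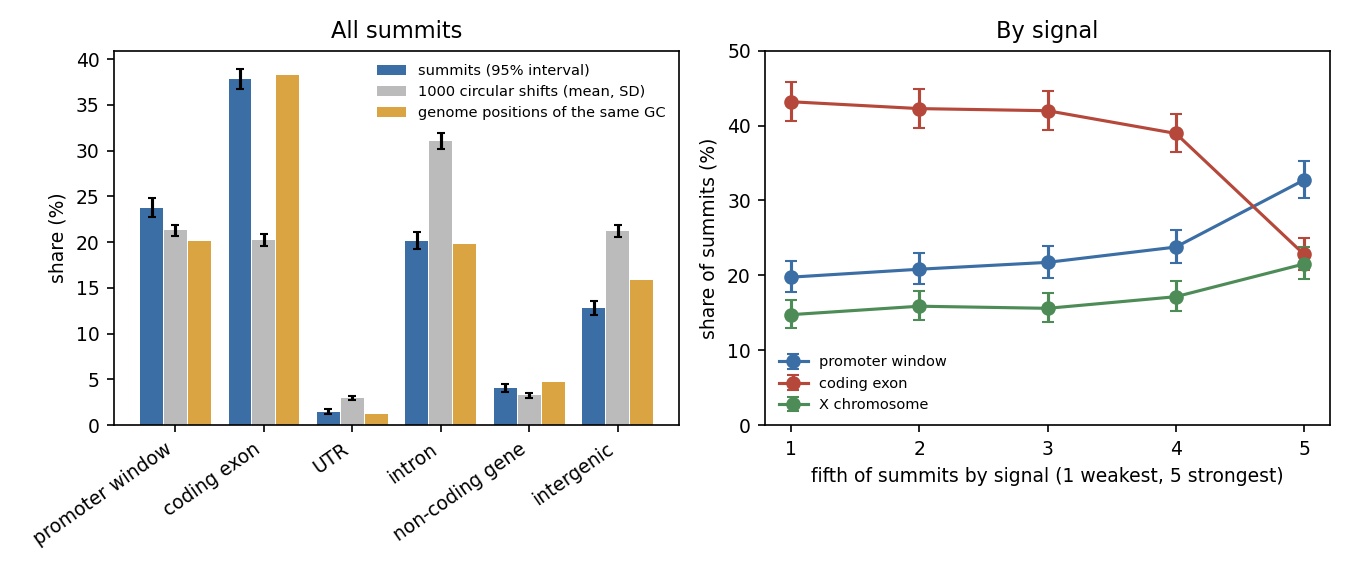
Left, share of summits in each annotated class (blue, with 95% Wilson intervals), the mean share after 1000 circular shifts (grey, with the SD of the shifts) and the share among genome positions of the same GC (yellow). Right, share of summits in promoter windows, in coding exons and on the X chromosome by signal, from the weakest 20% to the strongest 20%, with 95% intervals. Coding exons fall from 43.2% to 22.8% and promoter windows rise from 19.8% to 32.7%.

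The strongest summit (signal 783) lay on chromosome III at 10759280 of build ce11, in a peak from 10759005 to 10759563. It was 27 bp upstream of the 5' end of tasp-1, a homologue of the protease taspase, and also in the window of the divergent gene K01G5.10. Among the 15 strongest summits found in both replicates' own lists, 6 lay in promoter windows. The other 5 of these were at nhl-2, which encodes a TRIM-NHL protein, and tag-340 (shared summit, III 4899922, signal 749), at serp-1.1 (X 15841315, signal 738), at pde-6, a cyclic nucleotide phosphodiesterase gene, and Y95B8A.6 (shared summit, I 882833, signal 693), at hsp-3, which encodes an endoplasmic reticulum BiP chaperone (X 6092150, signal 688), and at ntl-2, a gene of the CCR4-NOT complex (II 4376933, signal 673). The 3 strongest summits outside all promoter windows were intergenic on chromosome IV at 8795250 (signal 782), at -2342 bp from the nearest 5' end, that of C33D9.3, in an intron of gei-4 on chromosome III at 349910 (signal 746), and in an intron of T28F4.1 on chromosome I at 7475213 (signal 730), where an annotated non-coding RNA gene, T28F4.7, also lies.

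At the tagged gene itself, zfh-2 (I 803368 to 834765), the conservative list had 18 summits within 5 kb of the gene. The strongest (I 818252, signal 375, rank 182 of 7085) lay in an intron 14884 bp downstream of the 5' end, and a summit of signal 125.2 lay 158 bp upstream of it. Replicate 1's own list had 13 summits there and replicate 2's had 14, and in both the intronic summit ranked highest among them (rank 197 of 4281 and rank 200 of 4696). The strain also carries an inserted unc-119(+) marker. At unc-119 (III 10902641 to 10908935), which acts in the nervous system, the conservative list had 1 summit, in an intron at 10905353 (signal 85.1, rank 5831), and neither replicate's own thresholded list had any. These are values with no test, and reads from the inserted tag or marker were not separated from reads of the native loci.

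**Figure D3:**
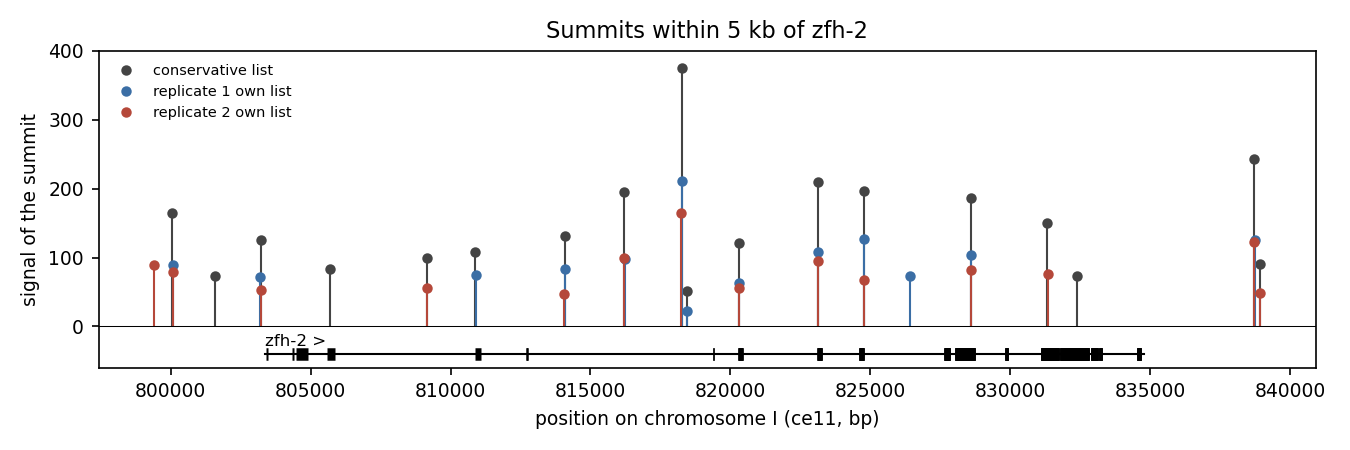
Summits within 5 kb of zfh-2 on chromosome I (x axis, position in bp, build ce11) with their signal as listed (y axis, shared by all lists), for the conservative list (dark), replicate 1's own list (blue) and replicate 2's own list (red). How the signal is scaled between lists is not given in the sources used here. The line below shows the gene with its coding exons as boxes, and the tallest summit, at 818252 with signal 375, lies in an intron.

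The X chromosome held 17% of all summits (1203 of 7085, 95% Wilson interval 16.1 to 17.9%), against 17.7% of the nuclear genome's length (exact binomial p = 0.131). Among summits in promoter windows the X chromosome held 19.8% (333 of 1684, 17.9 to 21.7%), against its 14.5% of all promoter window sequence (exact binomial p = 3.65e-09). The share of all summits on the X chromosome was 21.5% in the strongest 20% and 14.7% in the weakest 20%, an odds ratio of 1.59 (95% interval 1.3 to 1.93, Fisher's exact test, adjusted p = 8.06e-06). In replicate 1's own list the X chromosome held 19.3% of all summits, above its share of length (exact binomial p = 0.00534). In replicate 2's own list (18.1%, exact binomial p = 0.467) and the stronger 50% of peaks (18.4%, 0.252) no difference from the share of length was detected. Against genome positions of the same GC, chosen after seeing the data, the X chromosome would hold 16% of all summits (exact binomial p = 0.0264) and 15.6% of those in promoter windows (4.02e-06). Autosomes departed further from their share of length: I (18.4% of all summits against 15%), II (17.9% against 15.2%) and III (16.9% against 13.7%) above it, IV (14.1% against 17.4%) and V (15.8% against 20.9%) below it. The window share was not computed for autosomes, and the binomial tests treat summits as independent. Whether the window excess is particular to the X chromosome was therefore not tested.

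A summit in the promoter window was found for 1761 of 19973 protein-coding genes (8.82%), and the tissue and pathway lists fixed before the data were examined differed in how many members had one. By two-sided Fisher's exact tests adjusted over 29 lists, 5 lists had more such genes than the rest of the genome. Of the pan-neuronal genes, 11 of 28 (39.3%) had a summit, an odds ratio of 6.73 by the exact test (95% interval 2.84 to 15.3, adjusted p = 9.18e-05), and the strongest were at syd-2, which encodes the presynaptic scaffold liprin-alpha (signal 424), maco-1 (307), rgef-1, a Ras exchange factor gene (255), and aex-3 (246). Of the body wall muscle genes, 14 of 39 (35.9%) had a summit (exact test, odds ratio 5.83, 2.8 to 11.7, adjusted p = 2.86e-05), led by act-4, an actin gene (signal 374), unc-112, the kindlin gene (367), unc-60, which encodes cofilin (364), and unc-15, the paramyosin gene (335). Of the ribosomal protein genes, 28 of 77 (36.4%) had one (exact test, odds ratio 5.99, 3.61 to 9.75, adjusted p = 3.78e-10; odds ratio 3.99 in replicate 2's own list and 8.41 in replicate 1's), led by rpl-3 (signal 434), rpl-7 (355), rpl-15 (329) and rps-28 (307). Of the pharyngeal genes, 7 of 27 had a summit (exact test, odds ratio 3.63, 1.29 to 8.95, adjusted p = 0.0311), a call lost with the authors' other pooled list (odds ratio 2.33, adjusted p = 0.209), led by abu-14 (238), the FoxA gene pha-4 (151), the myosin light chain gene mlc-3 (144) and the T-box gene tbx-2 (143). Of the heterochronic genes, which time larval development, 5 of 14 had one (exact test, odds ratio 5.76, 1.51 to 19.2, adjusted p = 0.026), led by mab-10 (569), lin-66 (554), lin-14 (285) and kin-20 (250).

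Fewer members than expected had a summit in 2 large families. Of the seven-transmembrane chemoreceptor genes, 24 of 1239 (1.94%) did, against 9.27% of other genes (odds ratio 0.193, 95% interval 0.123 to 0.29, Fisher's exact test, adjusted p = 1.31e-23). The strongest were at sri-5 (signal 272), sri-71 (254), srab-10 (224) and sri-30 (213). Of the F-box genes, 12 of 322 (3.73%) did (exact test, odds ratio 0.396, 0.202 to 0.704, adjusted p = 0.00278), with the strongest at fbxa-176 (351), fbxb-7 (199), fbxa-66 (182) and fbxb-85 (176). The germline list had 5 of 57 genes with a summit (8.77%), the intestinal list 4 of 38, the epidermal and cuticle list 3 of 41, the ciliary list 3 of 46, the somatic gonad and vulva list 5 of 36, the homeobox list 14 genes (13.9%), and the major sperm protein (31 genes) and glial (18 genes) lists 0. None of these or of the other 14 lists passed the threshold. Among those 14, the neurotransmitter identity list had 3 of 30 genes with a summit (10%, odds ratio 1.15). The FLP and NLP neuropeptide list had 8 of 106 (7.55%, odds ratio 0.844). No excess like that of the pan-neuronal list was detected in either.

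GC content went with these counts. Genes were ranked by the highest GC content in their promoter window, read in stretches reaching 50 bp either side of each base. None of the lowest 20% had a summit, and 47.5% of the highest 10% did. Against 10000 random lists matched on that GC value in 50 groups of genes, a test chosen after seeing the data, the pan-neuronal list held 2.19 times the expected number (permutation test, adjusted p = 0.029), the ribosomal protein list 1.89 times (0.0029), the chemoreceptor list 0.401 times (0.0029) and the F-box list 0.488 times (0.00387). The body wall muscle (1.42 times, adjusted p = 0.321), pharyngeal (1.42 times, 0.551) and heterochronic (1.93 times, 0.307) lists did not pass in that permutation test. The heterochronic list also missed the threshold against lists matched on the distance to the upstream gene, where it held 3.92 times the expected number (permutation test, adjusted p = 0.0547).

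**Figure D4:**
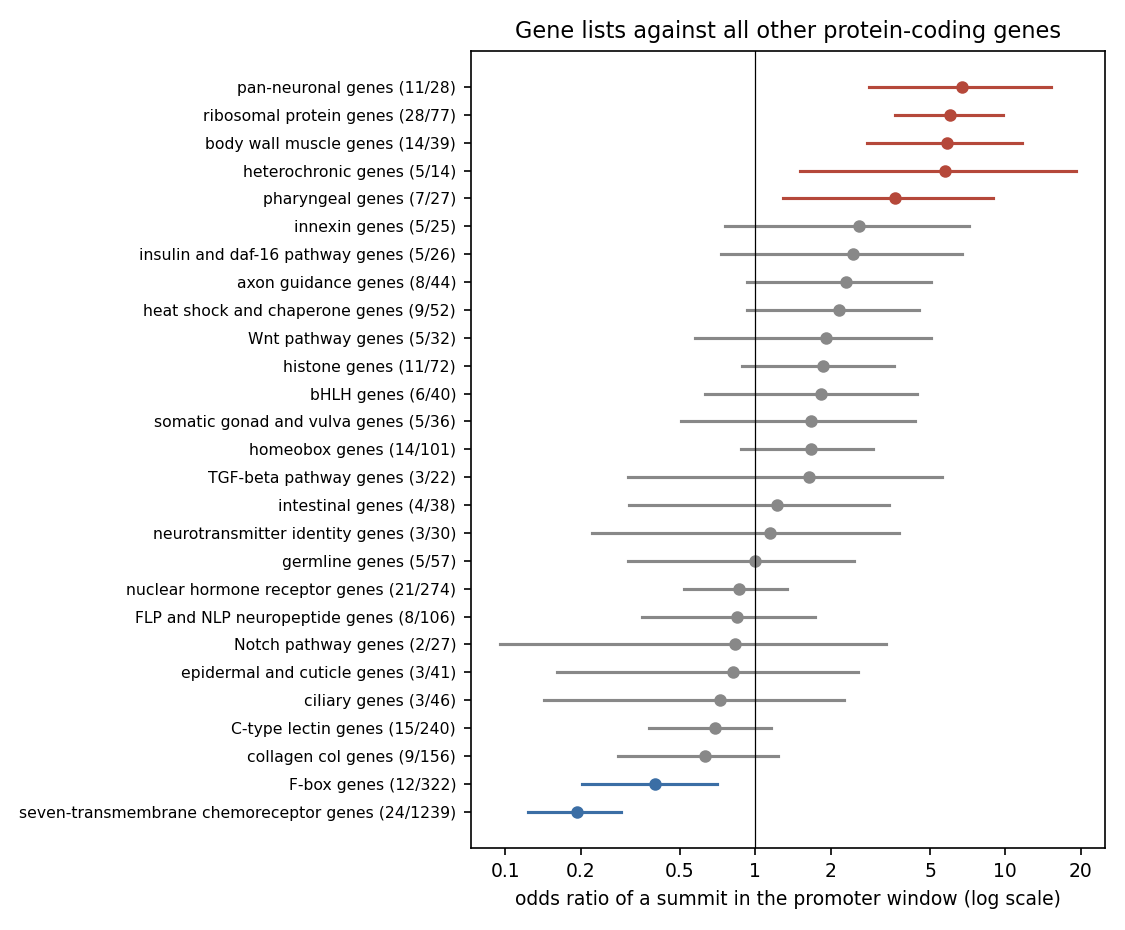
Odds ratio of having a summit in the promoter window for the members of each list against all other protein-coding genes (log x axis), with 95% intervals and the number of genes with a summit over the number measured. Red lists had more and blue lists fewer genes with a summit at an adjusted p under 0.05, grey lists did not pass, and the lists with 0 genes are not drawn. The chemoreceptor list has the lowest odds ratio (0.193) and the pan-neuronal list the highest (6.73).

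The sequence at summits was GC-rich. The sequence within 50 bp of a summit had a mean GC content of 55.1% ± 7 (SD over 7085 summits), against 39.6% ± 10.2 in windows centred 300 bp away and 35.4% in the nuclear genome, and 90.1% of summits had a higher GC content than their flank. The strongest 20% had a mean of 59.2% and the weakest 50.6%. The homeodomain core TAATTA was found within 50 bp of 0.692% of summits and in 3.9% of flanks (exact McNemar test, adjusted p = 2.71e-39), and 7 other AT-rich motifs were also less frequent at summits. The AT-motif after which vertebrate ATBF1 (ZFHX3) was named, GTTAATNATTAAC, occurred in 0 windows of either kind. It was also absent from shuffled copies of the summit windows, and no expected number was computed. With no match in any background, its absence says nothing about summits. Of 17 motifs, 6 were more frequent at summits than in flanks, 2 of them GC-containing control sequences. The largest ratio was that of the GA repeat GAGAGAGA, in 4.02% of summits and 1.03% of flanks (ratio 3.9, exact McNemar test, adjusted p = 1.24e-31). Against dinucleotide-shuffled copies of the summit windows, which keep their base composition, GAGAGAGA (ratio 2.26, adjusted p = 7.84e-18), the E-box forms CAGCTG (1.74, 5.6e-13) and CACGTG (1.61, 2.21e-06) stayed more frequent in the exact test. Neither control that was higher against flanks did, nor did CACCTG (1.01, exact test, adjusted p = 1). The AT-rich controls AATATT (2.45, adjusted p = 3.22e-07) and TATATA (2.62, 0.00244) and the motif TGACGTCA (4.91, 3.22e-07) were also more frequent than in shuffled copies by the exact test, so controls passed against both backgrounds. TAATTA did not differ from the shuffled copies (0.452%, exact test, adjusted p = 0.146).

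**Figure D5:**
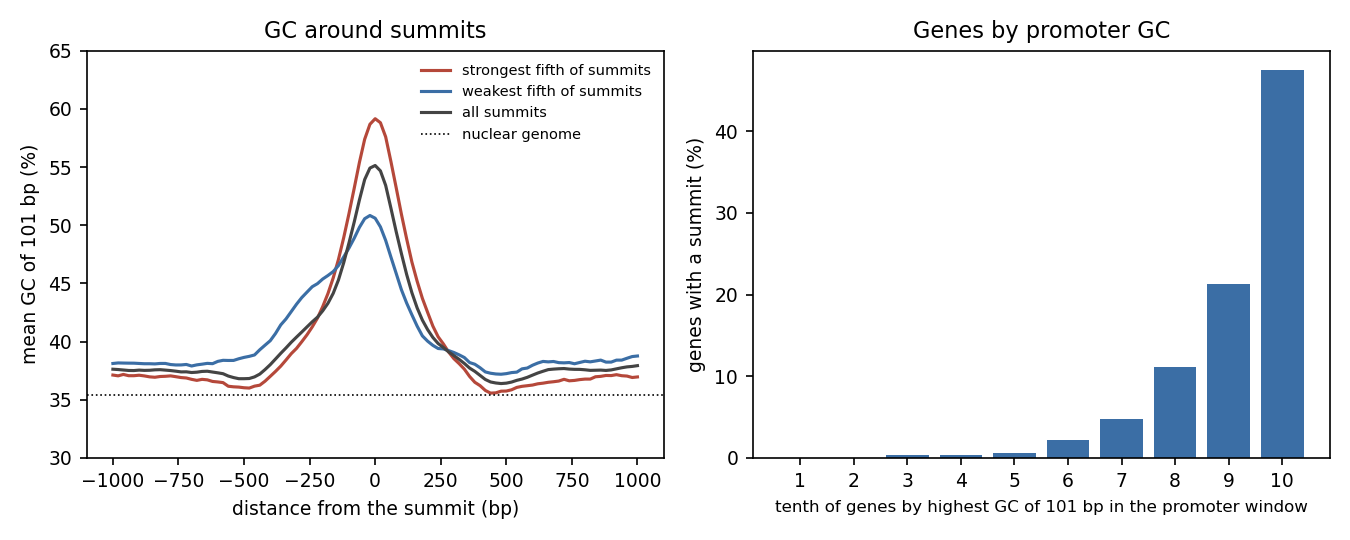
Left, mean GC content within 50 bp (y axis, %) by distance from the summit (x axis, bp) for the strongest 20%, the weakest 20% and all summits, with the nuclear genome as a dotted line at 35.4%. Right, percent of genes with a summit in the promoter window (bars) by the highest GC content in that window, in 10 equal groups of genes, which reaches 47.5% in the highest group.

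Most peaks called in 1 replicate only had a signal below their list's median. Of the 1010 peaks of replicate 1 with no overlap in replicate 2's list, 83.6% had a signal below their list's median, against 39.6% of shared peaks (Fisher's exact test, odds ratio 7.74, 95% interval 6.45 to 9.34, adjusted p = 4.33e-140), and for the 1378 such peaks of replicate 2 the shares were 77.2% and 38.7% (odds ratio 5.37, 4.64 to 6.22, adjusted p = 3.93e-132). The unshared peaks of replicate 2 lay in promoter windows less often than its shared ones (19.6% against 27.3%, odds ratio 0.65, Fisher's exact test, adjusted p = 3.3e-08), and no such difference was detected in replicate 1 (28.1% against 27.9%, odds ratio 1.01, 0.863 to 1.19, exact adjusted p = 0.873). They lay in coding exons more often in replicate 2 (47.2% against 32.7%, odds ratio 1.83, exact adjusted p = 4.28e-20) and less often in replicate 1 (27.5% against 31.4%, odds ratio 0.831, exact adjusted p = 0.0252). The difference between the replicates was not tested. The strongest unshared peaks of replicate 1 were on the X chromosome at 10766316, nearest to sma-9 (signal 208), in the window of the ribosomal protein gene rpl-35 (III 7854696, signal 181) and in an intron nearest to the 5' end of cfim-2 (IV 8927258, signal 164). Those of replicate 2 were in the window of ZC443.3 (V 12814678, signal 169), in a coding exon nearest to cut-2 (V 13415676, signal 163) and in an intron nearest to igcm-3 (X 2731620, signal 162). Of the unshared peaks, 93.4% in replicate 1 and 83% in replicate 2 overlapped a peak of the other replicate's longer ranked list. The ranked lists covered 12.8% (replicate 1) and 12.2% (replicate 2) of the genome, and no chance level was computed for this overlap. Of the peaks just named, those nearest to sma-9 and at ZC443.3 had a signal in the other ranked list (40.2 and 61.1). Those at rpl-35, cfim-2, cut-2 and igcm-3 had none listed there.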

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

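The tests matched on GC content or run with 1 summit per merged region, and the feature shares and locus counts in other lists, were chosen after seeing the data. The excess of summits near gene starts kept its direction and passed the threshold in all 9 alternatives run for it (1.05 to 1.32 times the expected share), as did the X chromosome excess among window summits in its 5. The pan-neuronal, ribosomal protein, chemoreceptor and F-box lists kept their direction and passed in all 13 alternatives each, with the ribosomal protein odds ratio at 3.99 to 8.41 in the lists of single replicates. The pharyngeal list missed the threshold with the other pooled list (odds ratio 2.33, Fisher's exact test, adjusted p = 0.209), and the heterochronic list when matched on the distance to the upstream gene (3.92 times the expected number, permutation test, adjusted p = 0.0547). Both, and the body wall muscle list, missed it when matched on GC. No paired analysis was possible because the samples form 1 group.

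Values that moved, with the cause not tested unless the setting itself gives it, were as follows. Genes with a summit numbered 1096 with the stronger 50% of peaks, 991 with a window of 500 bp upstream to 100 bp downstream, 3047 with 2000 bp upstream to 500 bp downstream and 3831 by the nearest 5' end within 5 kb, in each case by the setting's construction. Enriched lists numbered 10 by the nearest 5' end and 2 when matched on GC, in 10 groups of genes as in 50. Motifs less frequent at summits numbered 8 against flanks and 1 against shuffled windows, where base composition is held. That one, TGAGTCA, is not among the 8, of which AATATT and TATATA were more frequent than in shuffled windows. Those more frequent numbered 6 there too, but only GAGAGAGA, CACGTG and CAGCTG were shared with the 6 against flanks. Replicate overlap was 59.8% and 54.9% with reciprocal overlap of 0.5 of both peaks, and 70.2% and 64% for summits within 100 bp. Spearman's rho was 0.643 over the replicates' own ranked lists and 0.69 with 1 summit per merged region. Peaks numbered 4283 to 4696 and unc-119 summits 0 to 0 in the lists of single replicates. The X chromosome share of all summits lay above its share of length with the stronger 50% of peaks (18.4%) and in the lists of single replicates (18.1 to 19.3%). Against genome positions of the same GC, the feature ratios lay on the other side of 1 for coding exons (0.987, permutation p = 0.382), untranslated regions (1.12, 0.294) and introns (1.02, 0.462), with no difference detected, and for non-coding genes (0.865, 0.014), which passed the threshold. The planned correlation over the ranked list of both replicates was not run because its columns name no sample. Unknown depth limits any statement on absent peaks.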

Other observations

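The tests in this part were chosen after seeing the data, except those of the coding exon fall in shared peaks and in merged regions, whose outcomes were stated beforehand. For GC at summits, the explanation was narrowed from the sole factor to a main factor after the share of tiles in a peak (64.6%) was seen. The 10 further features below were tested on their own and overlap the promoter, exon and intron classes, so their counts differ from that of the non-coding gene class in the report. Genes annotated as ncRNA held 510 of 7085 summits (7.2%, 95% Wilson interval 6.62 to 7.82%), 6.81 times the share after circular shifts, against 3.66% of genome positions of the same GC (permutation test, adjusted p = 0.00666). They held 12.4% of the strongest 20% of summits and 3.53% of the weakest. Transfer RNA genes held 51 summits, 15.6 times the shifted share and 1.92 times the GC-matched share (permutation test, adjusted p = 0.00799). Pseudogenes held 127 summits, 0.467 times the GC-matched share (permutation test, adjusted p = 0.00666). Lower-case (masked) reference bases held 11% of summits, against 36% after shifts and 14.5% of genome positions of the same GC (permutation test, adjusted p = 0.00666). The snoRNA, snRNA, miRNA, lincRNA and piRNA genes held 10, 6, 10, 21 and 0 summits and did not pass against GC-matched positions (permutation test, adjusted p = 0.644, 0.921, 0.15, 0.151 and 0.921), where under 1 piRNA summit is expected. The central 50% of the chromosomes' length held 32.9% of summits, from 30.5% on chromosome I to 36.6% on the X chromosome, and genome positions of the same GC would place 34.9% there.

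The first pattern is the GC content at summits, 55.1% against 39.6% in the flanks, for which a candidate explanation is that base composition is a main factor in where peaks are listed. Of the genome tiles reaching 50 bp either side of their centre with at least the median summit's GC, 64.6% (95% Wilson interval 63.8 to 65.3%) lay in a peak of the ranked list of both replicates, against 11.8% of other tiles, and 40.9% lay in a conservative peak, against 1.83%, which lie on both sides of the 50% limit of this test and partly restate the pattern, so the test does not decide. GC within 50 bp as the only factor is argued against, since GC-rich coding exon tiles lay in a conservative peak 1.91 times as often as intergenic tiles of the same GC (49.6% and 26%). Coding exons do not carry the excess, as summits outside them had a mean GC of 54.5%. Whether the dependence comes from library preparation or sequencing, or from where ZFH-2::GFP binds, stays open, as no control library was analysed here and no biological explanation was tested.

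The second pattern is the high share of coding exons, which falls with signal. The overall share is near what GC content would give, with 37.8% of summits against 38.3% of genome positions with the summits' GC. This match cannot show that GC content accounts for the share, since it averages departures in opposite directions by signal. In the weakest 20% the share was 43.2% (95% Wilson interval 40.6 to 45.8%), above the GC-matched 37.8%. GC content does not account for the fall, because in the strongest 20% the GC-matched share was 37% and the observed share 22.8% (95% Wilson interval 20.7 to 25.1%). Peaks of 1 replicate alone are argued against, as the fall from the weakest to the strongest 20% was 24.3 percentage points (19.9 to 28.7) among summits that overlap both replicates' own lists. Further summits of the same interval are also argued against, as the fall was 23.8 points (20.3 to 27.4) with 1 summit per merged region, and what lies behind the fall stays open, with no biological explanation tested.

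The third pattern is the set of 7 gene lists past the threshold. Highest GC in the promoter window as the whole cause of all calls is argued against, within the limits of the test, since 4 of the 7 passed against lists matched on it. The matched lists drew genes singly, so clusters of neighbouring genes were not kept, which can make the p values too small. The matched test was not run on simulated data. Of the other 3 lists, which did not pass singly, body wall muscle, pharyngeal and heterochronic genes together had 26 genes with a summit, above the 11 to 24 (central 95%) of matched lists, with a mean of 17.4. These 3 were picked because they had passed the first test, which raises that number, and had not passed singly when matched on GC, which lowers it. The net effect of this choice was not tested, so a GC effect on them cannot be told apart from an excess. Expression in each tissue was not measured in these data, so a link between these lists and ZFH-2 activity may exist but stays a hypothesis.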
